A study of Mus musculus with 6 samples.

How the data were processed

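RNA was measured by sequencing of 6 mouse lung samples, 3 labelled as infected with a control hairpin lentivirus and 3 with a hairpin against Thoc1. Per the labels' protocols, RNA was purified with an RNeasy kit and libraries were made with a NEBNext Ultra kit. Per the submitters' processing notes the genome build was GRCm39, and the aligner and the counting tool are not given in the sources used here. Whether reads were counted by strand is not given either, so overlapping and antisense genes cannot be told apart. The authors deposited 1 table with a raw count per gene and library for 19639 genes, named by symbol, and the lowest total of a listed gene over the 6 libraries was 2. Per the file headers the authors' log2 fold changes and their standard errors come from a comparison with DESeq2's column names. The p-value and the adjusted p-value of each gene stand beside them in the deposited table. The same table holds a mean normalized count over all libraries, which was not used. All per-sample columns matched a sample title. Genome coordinates are not reported, since the reference at hand was of another build.

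Samples were grouped by their labels, and replicate numbers were given in the order of the records. They name a library and pair nothing. The titles of shThoc1 replicates 2 and 3 share their first number, which may or may not mean a shared animal, so these 2 libraries were also summed as an alternative. Every pair of libraries differed by more than sampling noise. The smallest chi-square per degree of freedom, over genes with at least 10 counts in the pair, was 20.4, between shThoc1 replicates 1 and 3. Among genes with a total count of at least 100, 127 had the same 6 counts as another gene, which marks overlapping or duplicated gene records. Ddx3y, on the Y chromosome, had 515 to 882 counts in the 6 libraries and Xist 3 to 15, so no library stood apart in sex. Total counts ran from 9934583 to 15025199 per library, and the shallowest was shThoc1 replicate 2.

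Genes were tested with the quasi-likelihood F-test of edgeR 4.0.16 (R 4.3.3), with the filter filterByExpr, TMM scaling, robust estimates and Benjamini-Hochberg adjustment over the 15287 genes that passed the filter. The other 4352 genes were not tested. The standard error of a log2 fold change was taken from the F statistic. CPM values use TMM-scaled library sizes. The common biological coefficient of variation was 0.480. Gene lists, 54 in all, were written before the data were examined, from knowledge of the field, and cover the TREX complex, RNA processing, tumour states, stress, metabolism and markers of the cells a piece of lung can hold. Of 1552 list entries 1527 were in the table, 13 of them through another symbol that was matched after the table's symbols were seen. The 50 lists with at least 5 tested members, leaving out the sex-linked and model genes, were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Beside this, camera with an estimated correlation and fry, a rotation test of whether the genes of a list move one way on balance, were run. A list's level in a library is the median log2(CPM + 0.5) of its members. An adjusted p under 0.05 counted as a call.

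The genes named in the text were set by a rule before the data were examined. It takes Thoc1, then genes with an adjusted p under 0.05, a log2 fold change of at least 1 in size, a mean log2 CPM of at least 1 and no overlap between the groups. Where none passes, it takes the 5 with the smallest unadjusted p in each direction. No gene passed, and the criteria of size, level and overlap were kept for these 5, a reading of the rule made after the data were seen. Unnamed and predicted genes, immunoglobulin and T cell receptor segments and sex-linked genes were left out of this step. For the TREX list and the lists called by camera, at most the 12 with the smallest p, the rule takes the 2 members with the smallest p. It adds Neurod1, Pou2f3, Yap1, Myc, Rb1 and Trp53, and a further gene that is not reported here. Other genes in the text were chosen after their values were seen.

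The code was tested on simulated counts for the 15287 genes, with 100 genes changed 2-fold and 100 changed 4-fold between 3 and 3 libraries. With the dispersions estimated from these libraries, edgeR recovered 0% of either set, and DESeq2 1.42.0 recovered 8% of the 2-fold and 68% of the 4-fold changes, with 62 of its 138 calls false (44.9%). With a dispersion of 0.04, edgeR recovered 64% and 100%, with 4.09% of calls false, and DESeq2 68% and 100%, with 13.4% false. The camera test called 1 of 49 unchanged lists at the estimated dispersions and 0 of 50 at a dispersion of 0.04, and it called a halved list in both. In these simulations genes varied independently, so they do not test the preset correlation.

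The alternatives were DESeq2 size factors and upper quartile scaling in edgeR, no filter, a stricter filter of at least 1 CPM in 3 libraries and a mean count of 50, estimates without the robust option, the DESeq2 Wald test, limma voom with sample quality weights, each library left out in turn, the summed libraries, an adjusted p under 0.1, a log2 fold change of at least 1, and lists without shared members. Those with the median of the G2/M list as a covariate and with edgeR's likelihood ratio test were added as alternatives over all genes after seeing the data. The covariate test of Thoc1 alone had been set beforehand. The 10 splits of the 6 libraries into 3 and 3 were each fitted in the same way. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.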

Results

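Gene-level RNA sequencing counts were obtained from 6 lung libraries of RPM mice. In this field the name denotes a mouse model of small cell lung cancer in which Rb1 and Trp53 are deleted and Myc is overexpressed. The animals had received lentivirus with a control hairpin (shControl, 3 libraries) or a hairpin against Thoc1 (shThoc1, 3 libraries). Thoc1 encodes a subunit of the THO complex, the core of the TREX complex that couples transcription to mRNA export. The comparison asks which transcripts differ in such lungs when Thoc1 is targeted. The total count was 13706926, 12617662 and 13479053 in shControl replicates 1, 2 and 3, and 15025199, 9934583 and 13923785 in shThoc1 replicates 1, 2 and 3. Of 19639 genes in the table, 15287 had enough counts to be tested. The labels do not say whether the 3 libraries of a group came from separate animals or how much of each piece was tumour, so p-values measure only the spread between these samples, which may be technical.

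Thoc1 mRNA was present at 83.9 ± 3.18 CPM, the count scaled to library size (SD, n = 3), in shControl and 61.4 ± 8.08 CPM (SD, n = 3) in shThoc1, so that 73.3% of the control level was left. The libraries held 85.7, 80.2 and 85.8 CPM in shControl and 53.4, 69.5 and 61.4 CPM in shThoc1, with no overlap between the groups. The log2 fold change of Thoc1 was −0.45 (SE 0.17) and did not pass edgeR's quasi-likelihood test (adjusted p = 0.304). An exact two-sided permutation test of the 6 log2(CPM + 0.5) values gave p = 0.1, the smallest that the 20 assignments of 3 against 3 libraries allow. Of the 17 tested members of the TREX list, 13 had a log2 fold change below 0, the median was −0.46, and the list fell in limma's camera test (adjusted p = 0.0147). Thoc1, the target of the hairpin, is 1 of these members, so the list is not independent of it. The list's level was 6.38, 6.16 and 6.43 log2(CPM + 0.5) in shControl replicates 1, 2 and 3. In shThoc1 replicates 1, 2 and 3 it was 5.46, 6.19 and 5.66, so the groups overlapped. Its members with the smallest p were Thoc3, at 42.6 ± 12.8 CPM in shControl and 20.8 ± 3.05 CPM in shThoc1, and the export adaptor Alyref, at 62.5 ± 15.1 and 31.6 ± 12.3 CPM (SD, n = 3 per group). Neither passed over all genes, and 0 members passed when adjusted over the list alone. The TREX list was not called with an estimated correlation (adjusted p = 0.678). Without shThoc1 replicate 1 its median was −0.28 and the call was lost (adjusted p = 0.131), and without shThoc1 replicate 2 its median was −0.69.

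**Figure D1:**
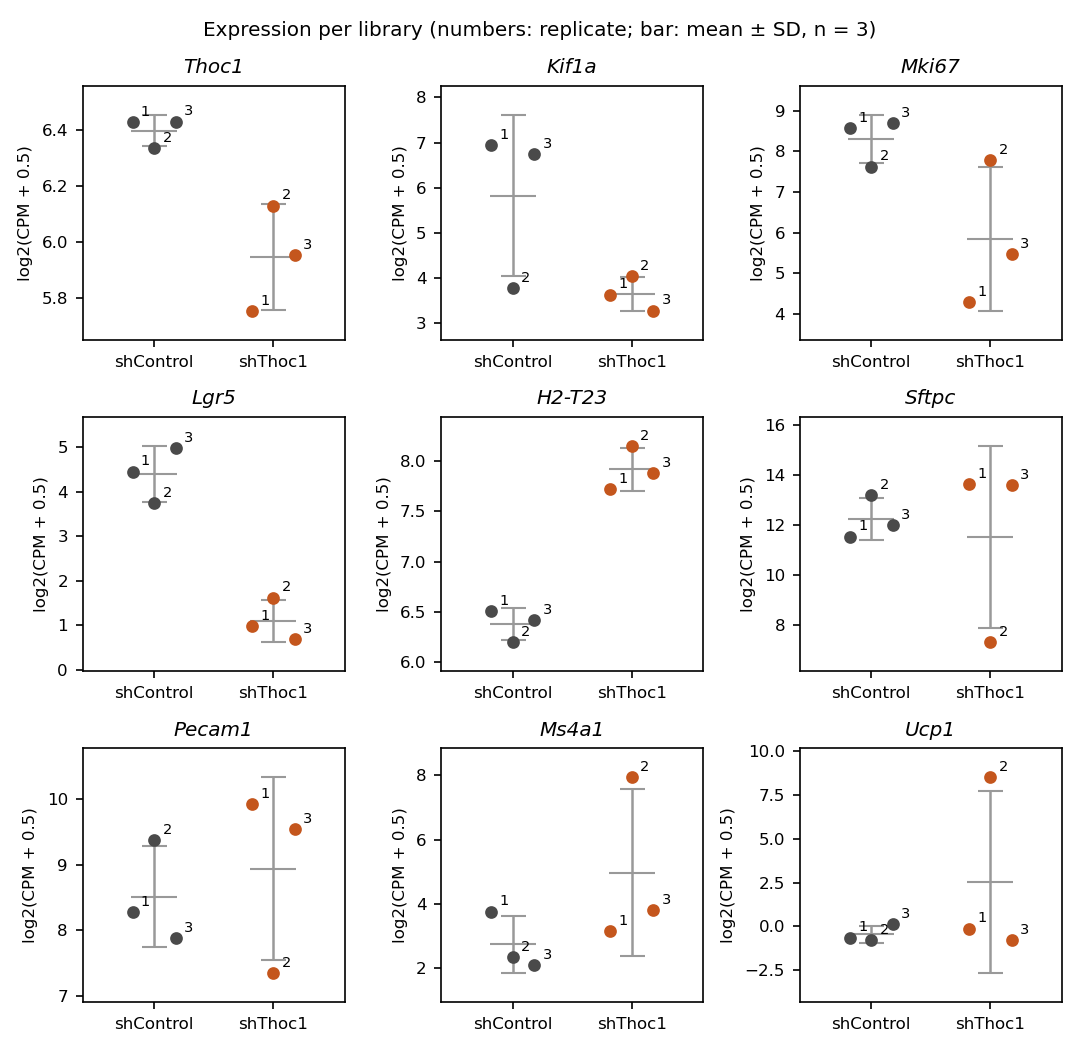
Expression of 9 genes in each library, as log2(CPM + 0.5) on the vertical axis, with shControl and shThoc1 on the horizontal axis. Points are libraries numbered by replicate and bars are the mean ± SD (n = 3). Thoc1 lay at 53.4 to 69.5 CPM in shThoc1 and at 80.2 to 85.8 CPM in shControl, whereas Ucp1 was at 361 CPM in shThoc1 replicate 2 and at 0.586 CPM or less in the other 5 libraries.

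Transcripts of the neuroendocrine tumour programme and of dividing cells were lower in shThoc1 as lists. All of the lists in this paragraph fell in the camera test, and none was called with an estimated correlation (adjusted p = 0.678 for each). The estimated correlation between the genes of a list ran from 0.39 for DNA damage to 0.92 for Myc targets, against the preset 0.01. Camera's adjusted p-values here and in later paragraphs use that preset, unless an estimated correlation is named. They are too small where the genes of a list vary together. Of 44 tested members of the neuroendocrine list, 41 had a log2 fold change below 0, with a median of −2.80 (adjusted p = 6.95e-07). The 9 tested members of the Neurod1 list were all below 0, with a median of −3.42 (adjusted p = 0.00621), a call that was lost with a stricter filter on low counts (median −3.52, adjusted p = 0.0614). In the G2/M list 53 of 55 members were below 0, with a median of −1.86 (adjusted p = 7.84e-23), and 26 had an unadjusted p under 0.05. In the S phase and DNA replication list 63 of 63 were below 0, with a median of −1.42 (adjusted p = 6.97e-20). The list of Myc targets and ribosome biogenesis genes had 50 of 50 members below 0, with a median of −1.15 (adjusted p = 2.42e-16). The DNA damage response list had a median of −0.44, with 34 of 44 members below 0 (adjusted p = 0.000743). No member of these 6 lists passed over all genes tested by edgeR or when adjusted over the list alone. The authors' deposited table, which holds a DESeq2-style comparison, has adjusted p under 0.05 for 12 lower members of the G2/M list, 7 each of the S phase and neuroendocrine lists, 4 of the Myc list, and 1 each of the Neurod1 and DNA damage lists.

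The members with the smallest p were Anln, an actin-binding protein of cytokinesis, at 62.7 ± 5.84 CPM in shControl and 17.5 ± 10.5 CPM in shThoc1, and Psrc1, at 22.5 ± 3.89 and 6.15 ± 2.98 CPM. The S phase regulator E2f1 was at 23.7 ± 7.79 and 8.40 ± 1.80 CPM, and the replication fork protein Tipin at 69.9 ± 13.3 and 25.7 ± 12.4 CPM. The ribosome biogenesis factor Rrs1 was at 50.1 ± 12.7 and 22.1 ± 4.54 CPM, and Cad, the enzyme that starts pyrimidine synthesis, at 54.9 ± 26.5 and 16.1 ± 5.59 CPM. The neuroendocrine secretory gene Vgf was at 4.93 ± 3.68 and 0.188 ± 0.267 CPM, and the neuronal kinesin Kif1a at 81.2 ± 59.4 and 12.4 ± 3.42 CPM (SD, n = 3 per group throughout). All had an adjusted p of 0.304 with edgeR. Neurod1 was at 11.8 ± 16.4 and 0.955 ± 1.65 CPM (adjusted p = 0.401). Myc was at 39.4 ± 13.4 and 16.3 ± 11.6 CPM (adjusted p = 0.317). Yap1, a marker of the non-neuroendocrine state, was at 80.2 ± 42.6 and 128 ± 74.0 CPM (adjusted p = 0.572), Rb1 at 50.7 ± 3.04 and 59.9 ± 7.97 CPM (adjusted p = 0.476) and Trp53 at 26.9 ± 10.2 and 46.5 ± 23.7 CPM (adjusted p = 0.390). The tuft cell factor Pou2f3 had 1 to 11 counts per library and was not tested.

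The libraries of a group did not share one level of this programme. The median of the neuroendocrine list was 5.74, 2.46 and 6.03 log2(CPM + 0.5) in shControl replicates 1, 2 and 3, and 0.52, 3.98 and 0.72 in shThoc1 replicates 1, 2 and 3. For the G2/M list the medians were 6.20, 5.35 and 6.13 in shControl and 2.11, 5.02 and 3.12 in shThoc1, without overlap. The groups overlapped for the other lists. The level in shThoc1 replicate 2 lay above that in shControl replicate 2 for S phase (4.95 against 4.70), Myc targets (6.20 against 5.82) and the Neurod1 list (2.39 against 0.89). For DNA damage it was 5.02 in shThoc1 replicate 2, above 4.93, 4.74 and 4.98 in shControl replicates 1, 2 and 3. Without shThoc1 replicate 2 the median log2 fold change was −5.74 for the neuroendocrine list, −7.36 for the Neurod1 list, −3.21 for G2/M, −2.31 for S phase and −0.81 for DNA damage. Leaving out each library in turn was planned before the data were examined. Of these fits, only the fit without shThoc1 replicate 2 called any gene, and its smallest adjusted p was 0.0488, close to the threshold. In it, 26 of 55 G2/M members, 10 of 63 S phase members, 3 of 50 Myc targets and 2 of 44 DNA damage genes passed over all genes. So did 1 of 44 neuroendocrine genes and 0 of 10 members of the Neurod1 list, and all that passed were lower. Without shControl replicate 1 the Neurod1 list had a median of −1.82, and the DNA damage list had a median of −0.24 without shThoc1 replicate 1 and −0.26 without shThoc1 replicate 3.

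Lists of RNA processing and translation were lower by smaller amounts. The core spliceosome list had 44 of 53 members below 0 and a median log2 fold change of −0.48 (adjusted p = 9.48e-07 by camera). Its members with the smallest p were the Sm protein gene Snrpd1, at 107 ± 20.9 CPM in shControl and 45.0 ± 21.9 CPM in shThoc1, and Lsm2, at 20.9 ± 3.79 and 10.2 ± 3.45 CPM. The list of nuclear pore and mRNA export genes had 27 of 31 members below 0 and a median of −0.40 (adjusted p = 5.13e-05), led by Eny2 at 130 ± 22.1 and 78.4 ± 8.93 CPM and the nucleoporin gene Nup155 at 77.7 ± 14.7 and 43.8 ± 12.9 CPM. Splicing regulators had 46 of 59 members below 0 and a median of −0.34 (adjusted p = 0.00274). Cytosolic ribosomal protein genes had 75 of 77 members below 0 and a median of −0.34 (adjusted p = 6.29e-06), with Rps2 at 1700 ± 139 and 1015 ± 486 CPM and Rpl29 at 126 ± 23.1 and 78.5 ± 36.5 CPM (SD, n = 3 per group). Genes of oxidative phosphorylation had 42 of 50 members below 0 and a median of −0.30 (adjusted p = 0.00395). No member of these 5 lists passed over all genes or when adjusted over the list alone. None was called with an estimated correlation, with adjusted p = 0.722 for oxidative phosphorylation and adjusted p = 0.678 for the other 4. In each of these 5 lists the level in shThoc1 replicate 2 lay above that in shControl replicate 2. In them and in the TREX list, as in the G2/M list, shThoc1 replicates 1 and 3 had the lowest levels. Whether these lists follow the share of dividing tumour cells was not tested. The core spliceosome level was 6.33, 5.93 and 6.31 log2(CPM + 0.5) in shControl replicates 1, 2 and 3. It was 5.62, 6.00 and 5.58 in shThoc1 replicates 1, 2 and 3. For ribosomal proteins the levels were 9.51, 9.56 and 9.79 in shControl and 8.72, 9.79 and 9.04 in shThoc1. Without shThoc1 replicate 2 the median log2 fold changes were −0.70 for the nuclear pore, −0.53 for splicing regulators, −0.76 for ribosomal proteins and −0.61 for oxidative phosphorylation. Without shThoc1 replicate 1 the ribosomal protein list had a median of −0.10 and was no longer called (adjusted p = 0.0768), and splicing regulators had a median of −0.19. The ribosomal protein list had a median of −0.19 without shThoc1 replicate 3. Oxidative phosphorylation was no longer called without shControl replicate 3 (median −0.13, adjusted p = 0.265), shThoc1 replicate 1 (median −0.10, adjusted p = 0.282) or shThoc1 replicate 3 (median −0.15, adjusted p = 0.0862).

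Antigen presentation genes were higher in shThoc1. All 23 tested members had a log2 fold change above 0, with a median of 0.98, and the list rose in the camera test (adjusted p = 3.84e-14). It was not called with an estimated correlation (adjusted p = 0.678). Of the 23 members, 0 passed over all genes tested and 16 passed when adjusted over the list alone, and 10 have adjusted p under 0.05 in the authors' deposited table, all of them higher. The nonclassical class I gene H2-T23 was at 82.9 ± 8.97 CPM in shControl and 242 ± 36.3 CPM in shThoc1 (log2 fold change 1.55, SE 0.20, adjusted p = 0.304), and the class II gene H2-Eb1 at 232 ± 46.4 and 570 ± 96.6 CPM (log2 fold change 1.30, SE 0.25, adjusted p = 0.304; SD, n = 3 per group). H2 genes belong to a multigene family, so reads can be split between near copies and single values are uncertain. Leaving out shThoc1 replicate 2 gave a median of 0.73, and the list was still called (adjusted p = 6.45e-08).

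Markers of lymphoid cells moved the same way. The T cell list had 24 of 24 members above 0 with a median of 2.61 (adjusted p = 2.24e-05), the B and plasma cell list 21 of 22 with a median of 2.17 (adjusted p = 2.24e-05), and the natural killer cell list 13 of 13 with a median of 1.98 (adjusted p = 2.24e-05). Dendritic cell markers had 15 of 17 members above 0 and a median of 1.10 (adjusted p = 0.00124). These 4 lists were not called with an estimated correlation (adjusted p = 0.678 for each). Their members did not pass over all genes, and Klrk1, the gene of the NKG2D receptor, was the 1 that passed when adjusted over the list alone, at 2.05 ± 0.0644 CPM in shControl and 6.90 ± 1.77 CPM in shThoc1. Nkg7 was at 0.605 ± 0.386 and 4.47 ± 4.05 CPM. Among T cell markers, Cd3g was at 8.01 ± 0.402 and 60.5 ± 72.4 CPM and Cd5 at 2.05 ± 0.621 and 19.96 ± 26.3 CPM. The immunoglobulin heavy chain gene Ighm was at 216 ± 61.8 and 804 ± 366 CPM and the plasma cell gene Mzb1 at 12.9 ± 3.74 and 49.2 ± 28.0 CPM (SD, n = 3 per group). Much of the difference in the list medians came from shThoc1 replicate 2, where Cd3g reached 144 CPM against 16.6 and 20.9 CPM in shThoc1 replicates 1 and 3. This did not hold for every marker. Ighm was at 1129, 875 and 407 CPM and Klrk1 at 6.32, 8.89 and 5.50 CPM in shThoc1 replicates 1, 2 and 3. Without shThoc1 replicate 2 the medians were 0.70 for T cells, 0.43 for B and plasma cells, 1.10 for natural killer cells and 0.53 for dendritic cells.

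Further lists were higher by the camera test, without a member that passed over all genes. Interferon-stimulated genes had 40 of 47 members above 0 and a median of 0.57 (adjusted p = 9.11e-05). Ciliated cell markers had 19 of 20 above 0 and a median of 0.57 (adjusted p = 6.76e-05), with Sec14l3 at 601 ± 241 CPM in shControl and 1363 ± 452 CPM in shThoc1 and Tppp3 at 155 ± 57.2 and 263 ± 12.8 CPM (SD, n = 3 per group). The median was 0.52 for inflammatory cytokines and chemokines (adjusted p = 0.0171), 0.26 for apoptosis genes (adjusted p = 0.00648), 0.94 for mesothelial cells (adjusted p = 0.0138), 1.28 for red blood cells (adjusted p = 0.0195), 0.89 for platelets (adjusted p = 0.0230), 0.58 for cardiac and skeletal muscle (adjusted p = 0.0121) and 3.27 for adipocytes (adjusted p = 0.0246). Genes of epithelial-mesenchymal transition were lower, with 21 of 28 members below 0 and a median of −0.80 (adjusted p = 0.0246). When adjusted over the list alone, Loxl2 and Fn1 of the latter list passed, as did Lipe and Adrb3 of the adipocyte list and no member of the others. In each of these 10 lists the levels of the groups overlapped. For inflammatory cytokines the highest level was in shControl replicate 1, at 3.73 log2(CPM + 0.5), against 3.15, 3.61 and 3.24 in shThoc1 replicates 1, 2 and 3. For muscle it was in shControl replicate 3, at 4.96 against 4.83, 3.81 and 4.19. With an estimated correlation none of the 10 lists was called (adjusted p = 0.681 for epithelial-mesenchymal transition and adjusted p = 0.678 for the rest). Most of these calls were lost in some alternative, which need not mean that the difference shrank. With sample quality weights the median was 1.35 for red blood cells, 0.65 for inflammatory cytokines and 0.87 for muscle, not smaller than without weights. It was 0.32 for interferon-stimulated genes, which was smaller. Without shControl replicate 2 the median was 1.41 for red blood cells and 3.12 for adipocytes. With sample quality weights the calls were lost for epithelial-mesenchymal transition (median 0.19, adjusted p = 0.946), interferon-stimulated genes (adjusted p = 0.0534), inflammatory cytokines (adjusted p = 0.0768), red blood cells (adjusted p = 0.179), muscle (adjusted p = 0.241) and adipocytes (median −0.24, adjusted p = 0.634), and the stricter filter ended the adipocyte call too (adjusted p = 0.146). Without shThoc1 replicate 2 the calls were lost for interferon-stimulated genes (median 0.18, adjusted p = 0.126), inflammatory cytokines (0.25, adjusted p = 0.0598), apoptosis (0.29, adjusted p = 0.0506), epithelial-mesenchymal transition (−0.50, adjusted p = 0.397) and adipocytes (−0.74, adjusted p = 0.613), and the ciliated cell median was 0.24. Without shControl replicate 1 the adipocyte call was lost (adjusted p = 0.0684), and the medians were 0.34 for ciliated cells and 0.17 for muscle. Without shControl replicate 2 the calls were lost for epithelial-mesenchymal transition (median 0.14, adjusted p = 0.988), red blood cells (adjusted p = 0.0727), muscle (median 0.01, adjusted p = 0.458) and adipocytes (adjusted p = 0.200), and the medians were 0.68 for apoptosis and 1.80 for mesothelial cells. Without shControl replicate 3 they were lost for inflammatory cytokines (median 0.29, adjusted p = 0.604), apoptosis (adjusted p = 0.0502) and mesothelial cells (median 0.63, adjusted p = 0.0938), and the medians were 0.34 for interferon-stimulated genes, 1.00 for ciliated cells and 2.26 for muscle. With shThoc1 replicates 2 and 3 summed, the call for epithelial-mesenchymal transition was lost (adjusted p = 0.0704). The platelet call was lost without shThoc1 replicate 1 (median 0.28, adjusted p = 0.229) or 3 (adjusted p = 0.0899). Without shThoc1 replicate 1 the medians were 0.90 for interferon-stimulated genes and 0.37 for muscle.

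**Figure D2:**
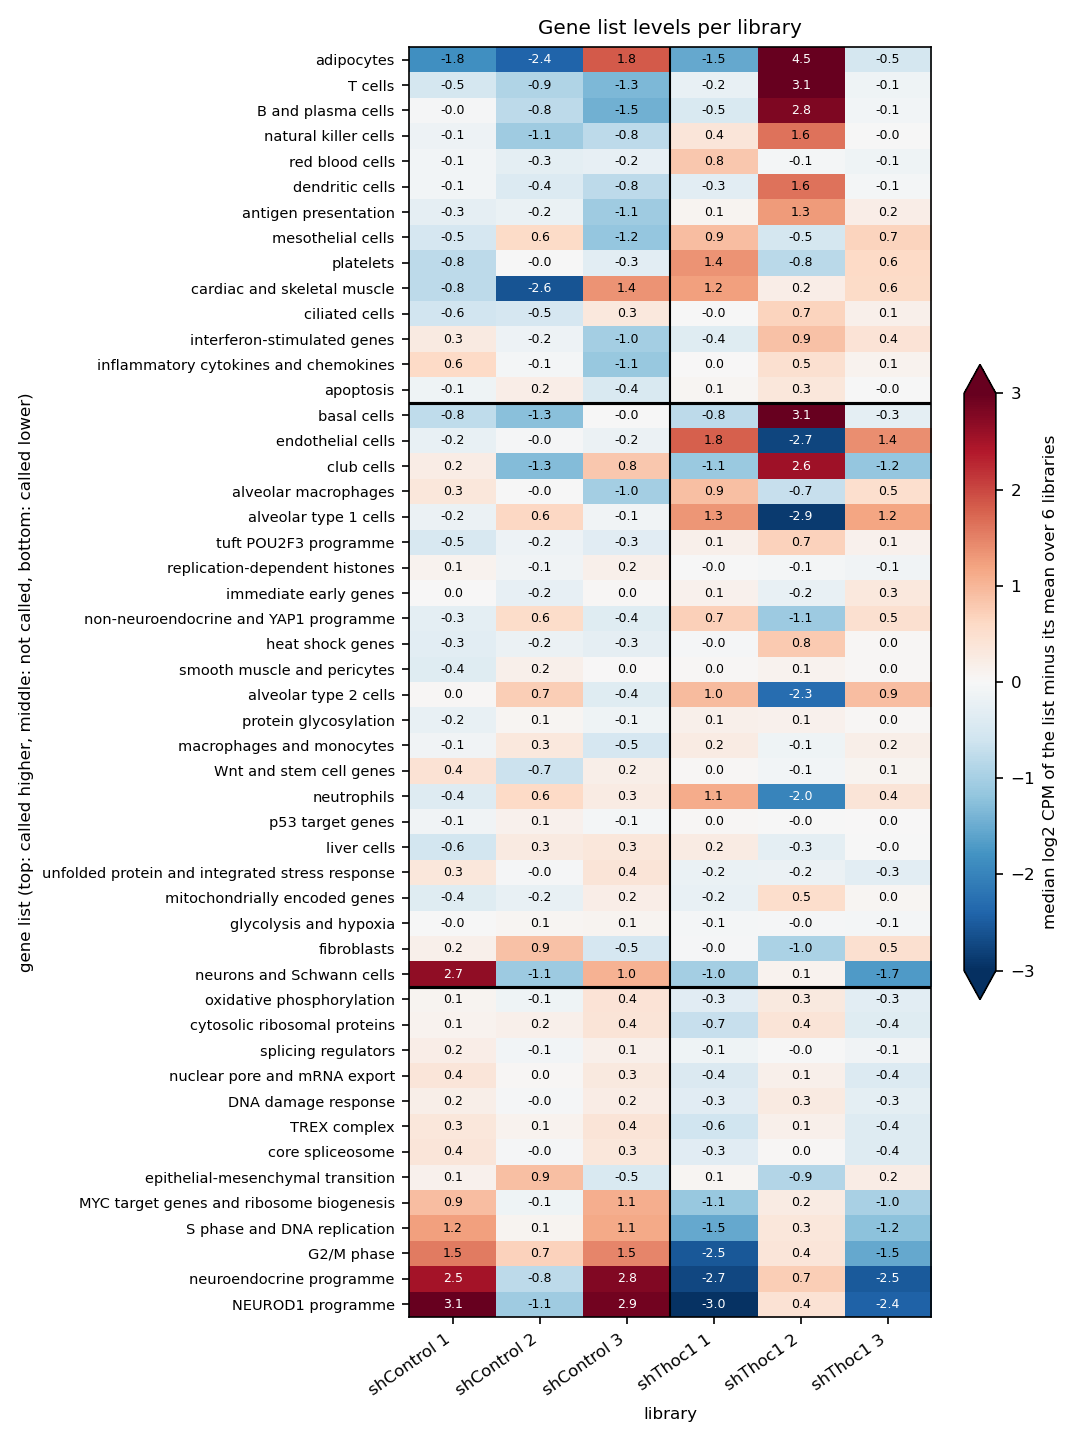
Median log2(CPM + 0.5) of each of the 50 tested gene lists (rows) in each of the 6 libraries (columns), minus the row's mean over the 6 libraries, with red above and blue below that mean. Black lines separate the 14 lists called higher, the 23 not called and the 13 called lower in shThoc1. In shThoc1 replicate 2 the neuroendocrine list had a median of 3.98 and the endothelial list one of 4.10, against 0.52 and 8.63 in shThoc1 replicate 1.

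The other cell type lists were not called by camera on 6 equally weighted libraries after edgeR's default filter. Endothelial markers had a median log2 fold change of 1.00 (adjusted p = 0.316) and alveolar type 1 markers one of 0.65 (adjusted p = 0.976). In both lists shThoc1 replicates 1 and 3 lay above shControl and shThoc1 replicate 2 below it, with medians of 8.63, 4.10 and 8.24 log2(CPM + 0.5) for endothelial markers in shThoc1 replicates 1, 2 and 3 and 6.63, 6.81 and 6.66 in shControl. Without shThoc1 replicate 2 the endothelial list rose (median 1.48, adjusted p = 2.10e-12), as did alveolar type 1 (1.12, adjusted p = 3.35e-06), alveolar type 2 (0.76, adjusted p = 0.00552), alveolar macrophages (1.08, adjusted p = 0.000735), neutrophils (0.40, adjusted p = 0.0490), non-neuroendocrine and Yap1 genes (0.44, adjusted p = 0.000735) and immediate early genes (0.16, adjusted p = 0.0314), and 7 of 27 endothelial markers passed over all genes. For the endothelial and alveolar type 1 lists, each other library left out gave a smaller median that was not called. The endothelial median was 0.39 without shThoc1 replicate 1 (adjusted p = 0.358 by camera). Alveolar type 1 had 0.15 without shThoc1 replicate 1 (adjusted p = 0.111) and 0.27 without shThoc1 replicate 3 (adjusted p = 0.161). The estimated correlation was 0.90 for endothelial and 0.92 for alveolar type 1 markers. With all 6 libraries the medians were 0.27 for alveolar type 2 cells (adjusted p = 0.654), 0.97 for club cells (adjusted p = 0.153), 2.42 for basal cells (adjusted p = 0.153), −0.31 for fibroblasts (adjusted p = 0.420), 0.28 for smooth muscle and pericytes (adjusted p = 0.519), 0.24 for macrophages and monocytes (adjusted p = 0.257), 0.78 for alveolar macrophages (adjusted p = 0.0628), 0.11 for neutrophils (adjusted p = 0.910), 0.08 for liver cells (adjusted p = 0.783) and −0.72 for neurons and Schwann cells (adjusted p = 0.316). Sample quality weights in limma voom, which give shThoc1 replicate 2 a weight of 0.139, called endothelial cells (1.58, adjusted p = 2.13e-06), alveolar type 1 cells (1.33, adjusted p = 0.00165), alveolar type 2 cells (1.08, adjusted p = 0.0326), alveolar macrophages (0.97, adjusted p = 0.0207) and non-neuroendocrine genes (0.80, adjusted p = 0.000186). Alveolar macrophages and basal cells were also called without the filter (adjusted p = 0.0282 and 0.0410) and on DESeq2's variance-stabilised values (adjusted p = 0.0392 and 0.0465). The titles of shThoc1 replicates 2 and 3 share a number, which may mark 1 animal. With these libraries summed, the lists of endothelial cells (1.22, adjusted p = 8.35e-10), alveolar type 1 cells (0.85, adjusted p = 0.000324), alveolar type 2 cells (0.44, adjusted p = 0.0411), alveolar macrophages (0.86, adjusted p = 0.00114), basal cells (2.15, adjusted p = 0.0224) and non-neuroendocrine genes (0.34, adjusted p = 0.0132) rose. Without shControl replicate 1 alveolar macrophages were called (median 1.21, adjusted p = 0.00325). Without shControl replicate 2 alveolar macrophages (0.94, adjusted p = 0.0476), non-neuroendocrine genes (0.76, adjusted p = 0.00122) and neurons and Schwann cells (−1.06, adjusted p = 0.0403) were. Club cells were called without shControl replicate 3 (1.80, adjusted p = 0.00628), basal cells without shThoc1 replicate 1 (3.19, adjusted p = 0.0275) or 3 (3.22, adjusted p = 0.0232), and fibroblasts without shThoc1 replicate 3 (−0.48, adjusted p = 0.0479).

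Among the remaining programmes, also not called in that setting, the median was 0.59 for tuft cell and Pou2f3 genes (adjusted p = 0.147), 0.29 for non-neuroendocrine and Yap1 genes (adjusted p = 0.208), 0.09 for p53 targets (adjusted p = 0.171), −0.30 for glycolysis and hypoxia (adjusted p = 0.0656), 0.28 for heat shock genes (adjusted p = 0.142), 0.31 for immediate early genes (adjusted p = 0.162), 0.07 for the unfolded protein and integrated stress response (adjusted p = 0.420), 0.26 for protein glycosylation (adjusted p = 0.153), 0.47 for replication-dependent histones (adjusted p = 0.316), 0.19 for Wnt and stem cell genes (adjusted p = 0.910) and 0.06 for mitochondrially encoded genes (adjusted p = 0.783). With shThoc1 replicates 2 and 3 summed, tuft cell genes (0.72, adjusted p = 0.0320) and immediate early genes (0.33, adjusted p = 0.0212) were called higher and glycolysis and hypoxia lower (−0.40, adjusted p = 0.0492). Quality weights called p53 targets (0.46, adjusted p = 0.0326), immediate early genes (0.44, adjusted p = 0.0410) and glycolysis and hypoxia (−0.54, adjusted p = 0.0326), and the last was also called without the filter (adjusted p = 0.0409). The median and the camera test differed in sign for the stress response, Wnt, alveolar type 2, neutrophil and liver lists. Without shControl replicate 2, p53 targets (0.41, adjusted p = 0.0178) and protein glycosylation (0.38, adjusted p = 0.0396) were called, and heat shock genes were without shControl replicate 3 (0.27, adjusted p = 0.0452), shThoc1 replicate 1 (0.27, adjusted p = 0.0153) or shThoc1 replicate 3 (0.30, adjusted p = 0.0449). In the Wnt list, Lgr5 and Sox4 passed when adjusted over the list alone. The lists of mast cells and of lymph node and thymus had 4 tested members each and were not tested as lists, nor were the 6 model genes and the 4 sex-linked genes.

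Gene by gene, the edgeR quasi-likelihood test called 0 genes higher and 0 lower, with a smallest adjusted p of 0.304. At an unadjusted p under 0.05 there were 1060 genes higher and 1413 lower, where chance would give 764 in all on average. The groups did not overlap for 21.6% of the tested genes, against 10% on average by chance for 3 against 3. Genes vary together, so a single grouping can stray far from these averages. The other splits of the libraries into 3 and 3 had 123 to 4799 genes at an unadjusted p under 0.05. The authors' deposited table has adjusted p under 0.05 for 326 higher and 590 lower genes. A separate run of DESeq2 on the same counts called the same 916 genes, which repeats that test and is not independent of it. Of the 875 that edgeR also tested, 873 had an unadjusted edgeR p under 0.05, again from the same 6 libraries. In the simulation with the dispersions estimated from these libraries, 44.9% of the DESeq2 calls were false. When shThoc1 replicate 2 was left out, edgeR called 112 genes higher and 146 lower, with a smallest adjusted p of 0.0488. It called 0 genes when any other single library was left out.

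The genes with the smallest p and a log2 fold change of at least 1 in size, none of which passed, were Lyz1, Gdpd3, H2-T23, Map4k2 and Rasa4 among those higher and Fbn1, Lgr5, Ctnnbip1, Ipo11 and Ipo11-lrrc70 among those lower. The lysozyme gene Lyz1 was at 44.7 ± 6.92 CPM in shControl and 141 ± 14.4 CPM in shThoc1 (log2 fold change 1.66, SE 0.19), and its near copy Lyz2 at 2424 ± 688 and 4966 ± 1686 CPM, so the share of Lyz1 reads that stem from Lyz2 is uncertain. Gdpd3 was at 51.7 ± 10.7 and 165 ± 7.59 CPM (log2 fold change 1.67, SE 0.20), the kinase gene Map4k2 at 73.1 ± 5.22 and 209 ± 43.9 CPM (1.52, SE 0.21) and the Ras GTPase activator gene Rasa4 at 10.9 ± 1.78 and 34.1 ± 4.83 CPM (1.64, SE 0.23). Fbn1, which encodes the matrix protein fibrillin-1, was at 194 ± 38.3 and 66.0 ± 6.79 CPM (log2 fold change −1.55, SE 0.22). The Wnt-regulated stem cell marker Lgr5 was at 21.8 ± 9.19 and 1.71 ± 0.759 CPM (−3.67, SE 0.51), and Ctnnbip1, an inhibitor of beta-catenin, at 26.9 ± 5.30 and 9.73 ± 0.740 CPM (−1.47, SE 0.24). The importin gene Ipo11 was at 73.7 ± 8.26 and 33.8 ± 4.72 CPM (−1.13, SE 0.19; SD, n = 3 per group throughout). The readthrough gene Ipo11-lrrc70 had identical counts to Ipo11 in all 6 libraries, so the 2 are 1 measurement. The adjusted p of each of these genes was 0.304 with edgeR, and in the authors' deposited table they range from 2.72e-09 for Lyz1 and Gdpd3 to 4.87e-05 for Ipo11. Each of them except Ctnnbip1 passed edgeR's test without shThoc1 replicate 2 (adjusted p = 0.0488).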

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

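As alternatives over all genes, the covariate fit and the likelihood ratio test were chosen after seeing the data, and the others before. The covariate test of Thoc1 alone had been set beforehand. Over the alternatives of scaling, filter, robust option, gene test, summed libraries and libraries left out, the named genes gave 495 results with the same direction and side of the threshold, 75 that newly passed, 0 that were lost and 0 that reversed. No named gene had passed with all 6 libraries and the quasi-likelihood test, so none could be lost. For the lists these were 627 the same, 38 newly called, 29 lost and 4 reversed, not counting the other list tests, thresholds and shared members. The direction of Thoc1 was the same in every alternative run. The number of genes called depended on the test. The DESeq2 Wald test called 326 higher and 590 lower, limma voom with sample quality weights called 3144 and 3709, and edgeR's likelihood ratio test called 85 and 145, against 0 and 0 with the quasi-likelihood test. The sample weights were 0.139 for shThoc1 replicate 2 and 0.359 for shControl replicate 2, against 1.12 to 4.42 for the other 4 libraries, so that fit rests mostly on those 4. Thoc1 passed with these weights (log2 fold change −0.54, adjusted p = 0.0144), and its adjusted p ran from 0.0719 to 0.785 in the other alternatives. With the G2/M covariate 1 gene was called higher, Tmem45b, and 0 lower. Tmem45b was at 47.8 CPM in shThoc1 replicate 2 and at 0 to 1.76 CPM in the other 5 libraries. Camera with an estimated correlation lost all 27 list calls (0 higher and 0 lower), and so did fry (0 and 0), whose smallest adjusted p was 0.343, with 4 lists at an unadjusted p under 0.05. With shThoc1 replicates 2 and 3, which share a title number, summed, 22 lists were called higher.

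Leaving out 1 library at a time gave 0 to 112 genes higher and 0 to 146 lower, and the upper ends came without shThoc1 replicate 2. These fits gave 13 to 17 lists higher, 10 to 13 lists lower and a log2 fold change of Thoc1 between −0.61 and −0.33. The alveolar type 2 list reversed in the camera test, from lower and not called to called higher, with quality weights (median 1.08), with the summed libraries (0.44) and without shThoc1 replicate 2, and its median ran from −0.13 to 0.78 over the libraries left out. The neutrophil list reversed without shThoc1 replicate 2, and its median ran from −0.64 to 0.40. Apart from the library left out, the cause of these changes and of those across tests was not tested. No paired analysis was possible because the replicate numbers follow the order of the records and the titles of the groups share only 1 number. Depth was not what kept edgeR from calling genes in the simulations, where the same depth with a dispersion of 0.04 gave 171 calls.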

Other observations

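The comparison of splits by unadjusted p and by DESeq2, and the tests of a common dilution and of fat and lymphoid tissue were chosen after the results were seen. The genes in the next 2 paragraphs were too.

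In shThoc1 replicate 2, some genes known from fat, lymphoid tissue and airways were high. The brown fat gene Ucp1 was at 361 CPM there and at 0.586 CPM or less in the other 5 libraries, the adipokine gene Adipoq at 147 against 7.10 CPM or less, and Cidea at 112 against 2.71 CPM or less. The B cell gene Ms4a1 was at 244 against 13.6 CPM or less, and Glycam1, a gene of high endothelial venules in lymph nodes, at 60.1 CPM against 0.0743 CPM or less. Among airway genes, Bpifa1 was at 8927 against 154 CPM or less and the basal cell keratin gene Krt5 at 45.2 against 1.17 CPM or less, whereas the club cell gene Scgb1a1, at 8985 CPM, lay within the range of the others (6756 to 21909 CPM). The alveolar gene Sftpc was at 161 CPM there and at 2983 to 12597 CPM in the others, and Ager at 14.7 against 591 to 1841 CPM.

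Without shThoc1 replicate 2, edgeR's quasi-likelihood test called endothelial genes among those higher, such as the angiopoietin receptor gene Tek (74.4 CPM in shControl and 419 CPM in shThoc1, adjusted p = 0.0488) and the transcription factor gene Sox7 (20.96 and 87.8 CPM, adjusted p = 0.0488). Among those lower were Tacc3, a spindle gene (51.5 and 6.94 CPM, adjusted p = 0.0488), and the repair gene Neil3 (22.5 and 1.96 CPM, adjusted p = 0.0488). With all 6 libraries these adjusted p-values were above 0.05, as for every gene tested. The light chain gene Iglc2 was at 12.9, 26.4 and 21.97 CPM in shControl and 334, 141 and 140 CPM in shThoc1, and the imprinted gene Grb10 at 432, 254 and 338 CPM and 84.0, 57.0 and 116 CPM.

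The 3 against 3 design gives 10 splits, too few for a share under 0.05. The quasi-likelihood test called 0 genes in every split, so its counts cannot rank the real split among the others. At an unadjusted p under 0.05 there were 2473 genes in the real split and at most 4799 in the others, with 2 of 10 splits as large. Camera called 27 lists in the real split and 19 to 27 in the others (2 of 10 as many), and DESeq2 called 916 genes and at most 3914 (2 of 10). The other split in each of these 2 of 10 sets shControl 1, shControl 3 and shThoc1 2 against shControl 2, shThoc1 1 and shThoc1 3, and it points to a structure of the samples that the hairpins do not follow. The first principal component, with 54.5% of the variance, put shControl 1, shControl 3 and shThoc1 2 at −74.0, −67.5 and −44.0 and shControl 2, shThoc1 1 and shThoc1 3 at 25.1, 85.6 and 74.8.

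A first pattern is that neuroendocrine and proliferation lists were lower in shThoc1. A dilution of the tumour by 1 common factor for every other cell type was examined in shThoc1 replicates 1 and 3 minus shControl. The list medians of 10 lung cell types spanned 2.79 log2 units, and the medians of the gene by gene differences spanned 1.496. These spans alone do not decide it. Club cells set the wider span, and mesothelial markers alone ran from 0.11 to 2.03 gene by gene over pairs of libraries. Gene by gene, endothelial markers stood at 1.58 (0.90 to 1.97 over pairs of libraries) and fibroblast markers at 0.09 (−0.43 to 0.55), while club cell markers stood at 0.30 gene by gene and at −1.05 by list median. The endothelial and fibroblast ranges do not overlap. These lists were picked as the extremes of the 10, and the pairs reuse the same libraries, so the gap does not decide for or against 1 shared factor. Pieces of lung that hold unequal amounts of tumour, each with its own surrounding tissue, stay open, as does an effect of the hairpin on the amount of tumour, since no label gives that amount.

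A second pattern is the lower level of Thoc1 in shThoc1. With the median of the G2/M list as a covariate its log2 fold change was −0.15 (SE 0.22), against −0.45 (SE 0.17) without. Its interval includes both 0 and the unadjusted value, so a knockdown and a Thoc1 level that may follow the share of dividing tumour cells cannot be told apart, because the covariate differs between the groups. The value lay nearer to 0 than the −0.2 set beforehand as the mark of the second, and its error was taken into account only after it was seen.

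The last pattern is that shThoc1 replicate 2 stands apart. Of 53 tested members of the adipocyte, B and plasma cell and T cell lists, 47 (88.7%) were higher in it than in each of the other 5 libraries, against 21.7% of all tested genes. By list these were 6 of 7, 17 of 22 and 24 of 24, and genes of a list vary together, so they are not independent counts. These lists were chosen after fat and lymphoid genes had been seen to be high in that library, so the share restates that observation and decides nothing. Fat and lymphoid tissue in that piece stays open. In each of the other 5 libraries, 47 of the 53 members were at 1 CPM or more, and 2 stood in another list too. An effect of the hairpin in that animal was not tested.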
